A study of Mus musculus with 16 samples.

How the data were processed

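The series holds RNA sequencing of GFP-positive and GFP-negative cells sorted from mouse intestinal tumours labelled AKVPL and AKVPSL, in 16 libraries. Per the labels' protocols, cells were sorted by flow cytometry and total RNA was isolated with a column kit. Markers used for gating, other than GFP, and the strand setting of the counting are not given in the sources used here. The submitters' processing notes name the aligner GSNAP and the genome build GRCm38, without versions. Per the file headers, the count of each gene is the number of reads that aligned uniquely to its gene model. The authors also deposited an RPKM value per gene, adjusted by a size factor per the file headers; how the size factor and the gene lengths were set is not given in the sources used here. Each library's values cover 36528 NCBI Gene IDs. Symbols and GRCm38 positions came from a RefSeq gene table of the patched release of that build, which matched 31049 IDs (85.0%). The 5479 unmatched IDs held 1.379% to 1.88% of a library's counts and stayed in library sizes and tests under their IDs.

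Groups were taken from the sample titles, 4 libraries per combination of genotype and sort. Replicates were compared before they were averaged: over genes with at least 10 counts the 24 pairs within groups differed by 9.05 to 73.58 times the sampling noise (chi-square per degree of freedom), so no library was counted as a repeat of another. Total counts ran from 10.881 to 41.602 M (M, 1e6 counts), with a median of 25.9 M. Mitochondrial genes took 3.55 ± 0.92% of counts (SD, n = 4) in AKVPL GFP-, 4.78 ± 1.52% in AKVPL GFP+, 4.09 ± 1.73% in AKVPSL GFP- and 2.44 ± 0.34% in AKVPSL GFP+.

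Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (18072 genes), libraries were scaled by TMM (factors 0.936 to 1.086), and 1 model with a mean per group was fitted to all 16 libraries with robust quasi-likelihood dispersions (12 residual degrees of freedom, biological coefficient of variation 0.182). The 5 contrasts were GFP+ against GFP- within each genotype, AKVPSL against AKVPL within each sort, and the difference between the sort effects. Two-sided quasi-likelihood F tests were adjusted by Benjamini-Hochberg over all genes of a contrast, with a threshold of 0.05. CPM values are TMM-scaled counts per 1e6 and are given as mean ± SD over 4 libraries, and log2 fold changes as estimate ± SE. The SE was calculated back from the test, as the absolute log2 fold change over the square root of the F statistic. It is approximate, above all for genes near 0 in 1 group. A group's counts were summed for genes with 3 or fewer counts in 1 of the groups: a fold against 0 is given as a lower bound with 3 counts over the group as the floor, and a fold against 1 to 3 counts with a 95% exact counting interval. These floors and intervals cover counting error only.

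Before the data were examined, 34 gene lists were written down, with markers of other cell types among them. Lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a contrast. The same test was run with the correlation estimated from the data, and fry beside it. The rule for named genes, also fixed beforehand, took Lgr5, Apc, Trp53 and Smad4, the 8 largest changes each way among genes past the threshold with a mean log2 CPM of at least 1 and groups that did not overlap, up to 4 members past the threshold from each list, and for the difference of sort effects the 5 genes with the smallest adjusted p each way. Predicted genes and unnamed clones were left out of the ranking. The rule names more genes than are printed, and the printed subset was picked after the values were seen. Some genes that the rule takes are not reported here. Xist, Col1a1, Lyz2, Epcam, Muc2, Isx, Krt36, Ly6g, the list members named because they moved against their list, and Cxcl10 lie outside the rule and were chosen after their values were seen.

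On simulated data for 18072 genes with 200 changed genes, drawn from the libraries' own means and sizes, the edgeR test recovered 156 for the sort in AKVPL, 161 for the sort in AKVPSL, 158 between genotypes in GFP+, 154 between genotypes in GFP- and 116 for the difference of sort effects. False calls were 4.88%, 3.59%, 2.47%, 5.52% and 4.92% of the calls. Of genes changed 2-fold, 74%, 78%, 82%, 76% and 50% were recovered in the same order. Of 200 random lists, 0 were called by camera in that test. The simulated genes were drawn independently of each other, so that count does not cover lists whose genes move together. In the data the correlation estimated for the mitosis list was 0.71 for the sort in AKVPL. Between 20.71% and 62.68% of genes changed in the data, so the recovered and false shares hold for the simulated setting only.

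Replicate numbers were checked for pairing by correlating deviations from the group means. GFP+ and GFP- libraries of the same number correlated by 0.256, 0.187, 0.209 and 0.131 in AKVPL and by 0.366, 0.324, 0.103 and 0.259 in AKVPSL, all above 0.1, so the numbers were taken to pair the sort comparisons. The pairing rests on these correlations and is not stated by the labels. In AKVPSL, GFP+ replicate 3 correlated best with GFP- replicate 4 and GFP+ replicate 4 with GFP- replicate 3. Across genotypes the correlations ran from -0.039 to 0.279, and those numbers were not taken as pairs. Several of them also lay above 0.1, so that limit alone does not tell pairs from other libraries.

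The alternatives fixed beforehand were DESeq2 size factors, library totals, no low-count filter, a filter at 5 CPM in at least 4 libraries, limma-voom, the DESeq2 1.42.0 Wald test, a fit of the compared groups alone, the replicate number as a block, the estimated correlation for lists, and each library left out in turn. After the data were seen, 2 were added: size factors from the epithelial identity list, and limma-trend on log2 of the deposited RPKM plus 1. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No reads were processed here.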

Results

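Gene expression was measured by RNA sequencing in cells sorted by GFP fluorescence from mouse intestinal tumours of 2 genotypes, labelled AKVPL and AKVPSL. Gating other than by GFP is not given, so the sorted cells may include cells other than tumour cells. The design text names the sorted populations by Lgr5, a receptor that marks stem cells of the intestinal crypt, and GFP is taken here as the reporter of that gene. The letters of the genotype names are not spelled out in the labels. Mouse intestinal tumour models named in this way combine changes in genes that include Apc, Trp53 and Smad4. The 2 names differ by the letter S. Each combination of genotype and sort had 4 libraries, 16 in all. With M for 1e6 counts, the total count per library ran from 10.881 M (AKVPL GFP- replicate 4) to 41.602 M (AKVPSL GFP+ replicate 1). Group means were 20.9 ± 7.25 M (SD, n = 4) in AKVPL GFP-, 27.7 ± 7.62 M in AKVPL GFP+, 25.3 ± 4.18 M in AKVPSL GFP- and 32.2 ± 6.98 M in AKVPSL GFP+. All 16 sample titles name the colon, while the tissue field read small intestine for 15 libraries and colon for 1 (AKVPSL GFP- replicate 1), so the labels do not settle the tissue of these libraries. The labels do not state that replicates came from separate animals or tumours, so the p-values measure the spread between these libraries, which may be partly technical. Over the 2000 most variable genes, the first principal component (67.9% of the variance) separated the genotypes and the second (22.92%) separated the sorts. Within each genotype the first component also parted GFP+ from GFP- libraries, so its share is not that of the genotype alone.

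The gene of the sort and the genes behind the genotype letters were examined first. Lgr5 (Gene ID 14160, GRCm38 chromosome 10, 115450314 to 115587780) stood at 296.5 ± 40 CPM (SD, n = 4) in AKVPL GFP+ against 65.7 ± 8.3 CPM in AKVPL GFP-, and at 269.8 ± 15 CPM in AKVPSL GFP+ against 67.7 ± 17.8 CPM in AKVPSL GFP-. Its log2 fold change was 2.18 ± 0.16 (SE) in AKVPL (edgeR adjusted p = 1.88e-08) and 1.99 ± 0.15 in AKVPSL (edgeR adjusted p = 1.17e-07). In each genotype the 4 GFP+ libraries lay above the 4 GFP- libraries. Lgr5 did not pass the threshold between the genotypes, with log2 differences of -0.14 ± 0.15 in GFP+ and 0.05 ± 0.15 in GFP- cells. Smad4 (Gene ID 17128, chromosome 18, 73634790 to 73703791) was not lower in the libraries labelled AKVPSL. It was 0.70 ± 0.11 log2 units higher there in GFP+ cells (247.6 ± 26.2 against 152.7 ± 4.24 CPM, edgeR adjusted p = 2.11e-05) and 0.37 ± 0.11 higher in GFP- cells (edgeR adjusted p = 0.00521). The GFP- difference was 0.03 and short of the threshold when libraries were scaled on the genes of the epithelial list, here called epithelial scaling. Counts over a whole gene cannot show a small edit or a deleted part that leaves the rest of the transcript. These values do not check the label, and the groups are called by their labels throughout.

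Apc (Gene ID 11789, chromosome 18, 34220297 to 34322190) was higher in GFP+ than in GFP- cells in AKVPSL, by 0.96 ± 0.18 log2 units (edgeR adjusted p = 0.000436). The corresponding value in AKVPL was 0.54 ± 0.18 (edgeR adjusted p = 0.0248). That call ended when any 1 of AKVPL GFP+ replicates 1 and 2 or AKVPL GFP- replicates 2 and 3 was left out (0.45 to 0.51). It also ended under 7 of the other settings, among them epithelial scaling, where the value was 0.18. In GFP+ cells Apc was 0.78 ± 0.18 higher in AKVPSL than in AKVPL. In GFP- cells the difference was 0.36 ± 0.18 and passed the threshold only without AKVPL GFP- replicate 4 (0.52) or AKVPSL GFP- replicate 3 (0.49). Trp53 (Gene ID 22059, chromosome 11, 69580348 to 69591873) passed the threshold in none of the 4 comparisons, with log2 values from -0.30 to -0.22. It did pass without AKVPSL GFP- replicate 4 for the sort in AKVPSL (-0.46), without AKVPL GFP- replicate 4 between genotypes in GFP- cells (-0.41), and with epithelial scaling for the sort in AKVPL (-0.53) and between genotypes in GFP- cells (-0.57).

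**Figure D1:**
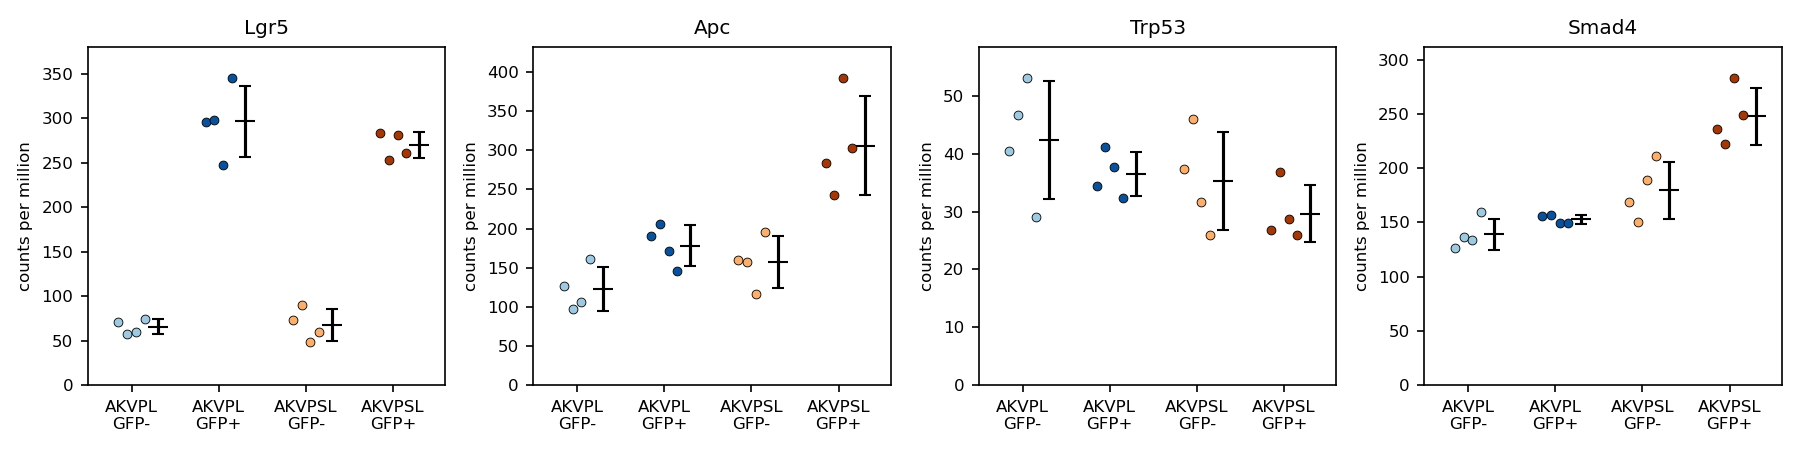
Levels of Lgr5, Apc, Trp53 and Smad4 in CPM (y axis, from 0) in the 4 groups (x axis); each point is 1 library, and the bar beside the points gives the mean and SD over 4 libraries. Lgr5 averages 296.5 and 269.8 CPM in the GFP+ groups against 65.7 and 67.7 CPM in the GFP- groups, and Smad4 is highest in AKVPSL GFP+ at 247.6 CPM.

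The first comparison asked how GFP+ cells differed from GFP- cells in AKVPL. GFP+ cells had more RNA of stem cell and proliferation genes, and GFP- cells had more RNA of stromal, vascular and leukocyte genes. The mitosis list, holding kinesins, cyclins and spindle proteins, rose in 24 of 24 members (also 24 when adjusted over the list alone), with a median log2 fold change of 1.44 (SD over genes 0.21). Nusap1, a spindle protein, rose by 1.65 ± 0.16 (SE) and Ube2c, a mitotic ubiquitin-conjugating enzyme, by 1.53 ± 0.15. The list passed camera's test (adjusted p = 1.71e-14) but not with an estimated correlation (adjusted p = 0.162 with an estimated correlation). Of 24 DNA replication genes 22 rose (22 adjusted over the list alone; median 0.74), among them Pola1 and Mcm6 at 1.26 ± 0.16 and 0.80 ± 0.12. Of 24 ribosome biogenesis genes 17 rose (19 adjusted over the list alone; median 0.39), including Polr1b, a subunit of RNA polymerase I, at 0.63 ± 0.09. For these lists camera's adjusted p was 3.80e-07 and 3.36e-05, and the adjusted p = 0.276 and 0.257 with an estimated correlation. With epithelial scaling the medians of DNA replication and ribosome biogenesis genes were 0.42 and 0.06.

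In the Lgr5 stem cell list 14 of 23 members rose and 2 fell (15 and 3 adjusted over the list alone) in AKVPL GFP+ cells, with a median of 0.53 (SD 0.81). Camera gave an adjusted p = 0.00093, against an adjusted p = 0.173 with an estimated correlation. With epithelial scaling the medians of the stem cell list and of the goblet cell list below were 0.19 and 0.22. Smoc2, Prom1 and Slc12a2, known crypt base genes, rose by 1.08 ± 0.09, 0.98 ± 0.10 and 1.26 ± 0.13, while Clca3b and Slc14a1 were the members that fell. The list includes Lgr5 itself, the gene of the sort. Lyz1, the lysozyme of Paneth cells, was among the genes with the largest rise (2.28 ± 0.50), with Bglap3 (2.93 ± 0.40), Pgc (2.72 ± 0.37) and S100g, a calcium-binding protein of the absorptive epithelium (2.29 ± 0.43). Of 18 goblet cell genes 7 rose and none fell (7 adjusted over the list alone; camera adjusted p = 0.0321, and adjusted p = 0.195 with an estimated correlation), led by Muc4 (1.84 ± 0.20) and Spdef, a transcription factor of secretory cells (1.23 ± 0.15). That list's call ended without AKVPL GFP+ replicate 3 (median 0.51) or AKVPL GFP- replicate 1 (0.57). Of 6 Paneth cell genes 3 rose, and the list passed camera's test only with no low-count filter (median 0.49) and with epithelial scaling (0.26). These 6 are the tested part of a list of 12, whose defensin genes were too low for the filter.

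The genes with the largest fall in AKVPL GFP+ cells included Tpsab1 (-6.88 ± 0.91), Cma1 (-6.38 ± 0.85), Cpa3 (-5.89 ± 0.84) and Mcpt4 (-5.62 ± 0.63), which encode proteases of mast cells, a cell type for which no list was tested. Fcrla (-5.25 ± 0.42), Sprr2h (-5.18 ± 0.87) and the chemokine Ccl17 (-5.12 ± 0.40) were also among them. The marker lists of other cell types fell as groups. Of 22 leukocyte genes 20 fell (median -2.70, SD 0.76), of 20 fibroblast genes 18 (median -3.29, SD 1.18) and of 14 endothelial genes 13 (median -3.23, SD 1.28), none rose, and the counts adjusted over the list alone were 21, 18 and 13. The camera test gave an adjusted p of 5.07e-14, 5.73e-16 and 6.90e-09, with an adjusted p = 0.162 with an estimated correlation for each. Cd74, the invariant chain of antigen-presenting cells, stood at 179 ± 81.3 CPM (SD, n = 4) in GFP+ and 2428 ± 883.8 CPM in GFP- cells, and the collagen gene Col1a1 at 243 ± 85.3 and 2413 ± 892.1 CPM. Xist, which female cells with an inactive X chromosome transcribe, stood at 12.8 ± 5.50 CPM in GFP+ and 99.9 ± 24.2 CPM in GFP- cells (log2 fold change -2.97 ± 0.38, edgeR adjusted p = 4.36e-05). Beside these markers fell the mesenchymal programme list (10 of 11, also 10 adjusted over the list alone, median -2.71), with Vim at -3.09 ± 0.34 and Twist1 at -3.21 ± 0.29. So did the TGF-beta target list (12 of 21, 1 rose, 12 and 1 adjusted over the list alone, median -0.72) and the antigen presentation list (11 of 16, also 11 adjusted over the list alone, median -1.59). In that order camera's adjusted p was 6.90e-09, 2.83e-07 and 6.90e-09, and for each the adjusted p = 0.162 with an estimated correlation. Of 24 genes of hypoxia and glycolysis 16 fell and none rose (20 adjusted over the list alone, median -0.53, camera adjusted p = 1.26e-06, and adjusted p = 0.257 with an estimated correlation), including P4ha1 (-1.22 ± 0.12) and the glucose transporter Slc2a1 (-1.01 ± 0.16); with epithelial scaling the median was -0.88. BMP target genes fell in 6 of 13 and rose in none (7 fell adjusted over the list alone, median -0.68, camera adjusted p = 0.00155, and adjusted p = 0.162 with an estimated correlation). Epithelial identity genes rose in 9 of 18 (9 adjusted over the list alone, median 0.27, SD 0.46, camera adjusted p = 0.0024, and adjusted p = 0.186 with an estimated correlation), for example Cdh17 by 1.15 ± 0.15. By construction their median was near 0 with epithelial scaling (-0.06). Interferon response genes rose in 6 of 24 and fell in none (6 adjusted over the list alone, median 0.29, SD 0.31). Camera gave that list an adjusted p = 0.0162 and an adjusted p = 0.513 with an estimated correlation. Its call ended with the DESeq2 Wald test, and its median was -0.03 with epithelial scaling.

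In total 7070 of 18072 genes changed between GFP+ and GFP- cells of AKVPL (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 4089 higher and 2981 lower in GFP+. At 2-fold or more, 532 were higher and 2116 lower. All 4 libraries of one sort lay above the other 4 for 41.2% of genes, where chance gives 2.857%. The share of calls that were higher in GFP+ depended on scaling. It was 57.84% with TMM, 42.09% with DESeq2 size factors, 44.87% with library totals and 12.22% with epithelial size factors, which moved the median of all genes by -0.33.

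**Figure D2:**
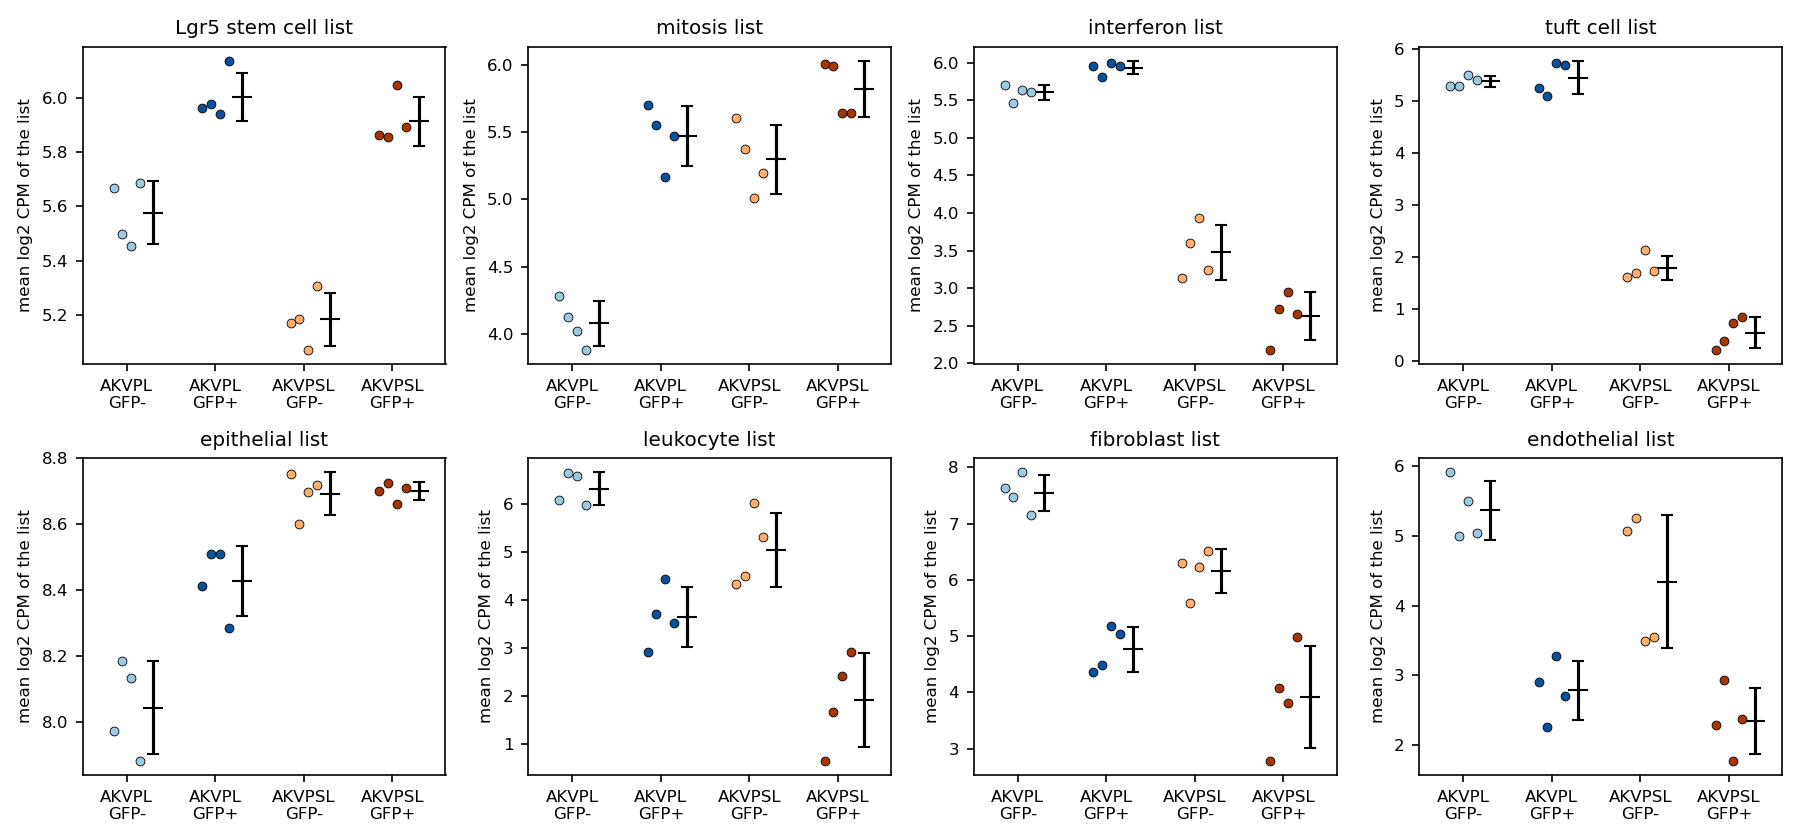
Mean log2 CPM over the genes of 8 lists (y axis, own range in each panel) in the 4 groups (x axis); each point is 1 library, and the bar beside the points gives the mean and SD over 4 libraries. The interferon and tuft cell lists separate the genotypes, and the leukocyte, fibroblast and endothelial lists are higher in the GFP- groups; in AKVPSL GFP- the endothelial list runs from 3.50 to 5.25.

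The second comparison asked the same of AKVPSL. GFP+ cells again had more RNA of stem cell genes, with secretory genes of Paneth and goblet cells, while GFP- cells had more RNA of fetal and regenerative genes and of leukocyte, fibroblast and endothelial markers. In the Lgr5 stem cell list 17 of 23 members rose and none fell (17 and 1 adjusted over the list alone), with a median of 0.78 (SD 0.75). Camera gave an adjusted p = 3.42e-08, and an adjusted p = 0.232 with an estimated correlation. Smoc2 rose by 1.56 ± 0.09 (SE), Prom1 by 1.07 ± 0.10 and Clca3b by 2.04 ± 0.22. Of 6 Paneth cell genes 5 rose and Nupr1, a stress-response gene, fell (5 and 1 adjusted over the list alone; median 2.41, SD 1.87). The defensin genes of that list of 12 were too low to be tested. Lyz1 rose by 3.91 ± 0.55, Ang4 by 3.46 ± 0.71, Reg4 by 3.16 ± 0.17 and Mmp7, which activates Paneth cell defensins, by 1.65 ± 0.12. Of 18 goblet cell genes 9 rose and none fell (9 adjusted over the list alone; median 0.63), with Tff3 at 2.58 ± 0.26 and Spink4 at 1.97 ± 0.24. Camera gave the Paneth and goblet cell lists an adjusted p = 0.00134 and 0.000671, and the adjusted p = 0.274 and 0.270 with an estimated correlation. Of 24 WNT target genes 12 rose and 2 fell (12 and 2 adjusted over the list alone; median 0.40), among them Rnf43 at 1.05 ± 0.12 (camera adjusted p = 0.000552, and adjusted p = 0.274 with an estimated correlation). The mitosis list rose in 16 of 24 (17 adjusted over the list alone; median 0.53, SD 0.37, camera adjusted p = 8.17e-05, and adjusted p = 0.433 with an estimated correlation), with Kif11 at 1.14 ± 0.17 and Nusap1 at 0.94 ± 0.15. Of the DNA replication genes 5 of 24 rose (1 adjusted over the list alone). That list passed camera's test only without AKVPSL GFP+ replicate 3 (median 0.24), AKVPSL GFP+ replicate 4 (0.24) or AKVPSL GFP- replicate 1 (0.17).

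Of 16 fetal and regenerative genes 10 fell in AKVPSL GFP+ cells and 1 rose (11 and 1 adjusted over the list alone; median -0.87, SD 0.82, camera adjusted p = 0.000395, and adjusted p = 0.274 with an estimated correlation). Krt7 fell from 2467 to 1122 CPM (-1.14 ± 0.09), Anxa3 from 929.7 to 419.5 CPM (-1.15 ± 0.10), Ly6a, known as Sca-1, from 1058 to 434.7 CPM (-1.28 ± 0.12), and Ly6d by -1.49 ± 0.16 on the log2 scale. Tuft cell genes fell in 10 of 17 (10 adjusted over the list alone; median -1.27, camera adjusted p = 0.000637, and adjusted p = 0.349 with an estimated correlation) from low levels, Dclk1 from 1.98 to 0.49 CPM and Hpgds, a prostaglandin synthase that leukocytes also express, by -2.54 ± 0.33. The Dclk1 call ended on the deposited RPKM values (-0.13 on the log2 scale of RPKM plus 1). Of 24 interferon response genes 14 fell and none rose (15 adjusted over the list alone; median -0.86), with Ifit3 at -2.44 ± 0.33 and Irf7 at -1.40 ± 0.20. Of 16 antigen presentation genes 14 fell (14 adjusted over the list alone; median -2.89), with Nlrc5, the activator of class I genes, at -3.17 ± 0.25. These lists had a camera adjusted p = 0.000552 and 4.09e-09, and the adjusted p = 0.411 and 0.274 with an estimated correlation. Id1 and Id3, targets of BMP signalling, fell by -1.34 ± 0.18 and -1.37 ± 0.13 on the log2 scale, while the BMP target list as a whole (2 of 13 rose and 7 fell) passed only with the DESeq2 Wald test (median -0.35). MAPK output genes rose in 7 of 19 and fell in 2 (7 and 2 adjusted over the list alone, median 0.35, camera adjusted p = 0.036, and adjusted p = 0.411 with an estimated correlation), a call that ended without AKVPSL GFP- replicate 3 (median 0.27); without AKVPSL GFP- replicate 4 the median was 0.20.

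Markers of other cell types were lower in AKVPSL GFP+ cells. Of 22 leukocyte genes 21 fell (21 adjusted over the list alone; median -3.34, SD 0.84), of 20 fibroblast genes 19 (19 adjusted over the list alone; median -2.21, SD 0.72) and of 14 endothelial genes 11, with 1 that rose (11 and 1 adjusted over the list alone; median -2.96, SD 1.60). For the 3 lists camera's adjusted p was 9.03e-10, 1.03e-09 and 0.0029, and the adjusted p = 0.274, 0.274 and 0.440 with an estimated correlation. Cd74 stood at 24.3 ± 11.9 CPM (SD, n = 4) in GFP+ and 432 ± 187 CPM in GFP- cells, and Xist at 5.52 ± 2.55 and 38.8 ± 7.85 CPM (log2 fold change -2.83 ± 0.39, edgeR adjusted p = 7.47e-05). The largest falls included the mast cell gene Tpsb2 (-5.69 ± 0.88), Ccl17 (-6.01 ± 0.56) and Cpa4 (-6.45 ± 0.72). Tph1, the enzyme of serotonin synthesis, had 2 counts over the GFP+ group against 130 in GFP-, 82.7-fold lower with a 95% counting interval of 22.5 to 690.5. Il12b had 3 against 142, 60.3-fold lower with an interval of 20.2 to 295.6. The Il12b call ended on the deposited RPKM values (-0.57 on that scale). Mesenchymal programme genes fell in 9 of 11 with 1 that rose (9 and 1 adjusted over the list alone; median -2.31), TGF-beta targets in 15 of 21 with 1 that rose (15 and 1 adjusted over the list alone; median -0.79) and hypoxia and glycolysis genes in 13 of 24 with 1 that rose (14 and 1 adjusted over the list alone; median -0.52). Camera's test gave an adjusted p of 0.000664, 0.000256 and 0.000598, and the adjusted p = 0.274, 0.304 and 0.440 with an estimated correlation. The epithelial identity list did not pass camera's test, with 4 genes that rose and 5 that fell of 18 (median 0.07).

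In AKVPSL 8494 of 18072 genes changed between the sorts by edgeR's quasi-likelihood test, 4053 higher and 4441 lower in GFP+, of which 840 and 2219 by 2-fold or more. The groups did not overlap for 39.13% of genes, where chance gives 2.857%. Higher genes made up 47.72% of the calls with TMM and 37.48% with epithelial size factors. Without the library whose tissue field read colon, 7903 genes were called. Both genotypes gave the same direction for 1702 genes higher and 2014 lower in GFP+, where independent lists of these sizes would share 917.0 and 732.5, and 466 genes were called in opposite directions.

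The difference between the 2 sort effects was tested directly. Mitosis genes were raised less in GFP+ cells of AKVPSL than of AKVPL: the difference of log2 fold changes was below 0 past the threshold for 18 of 24 (23 adjusted over the list alone), with a median of -0.92 (SD 0.26, camera adjusted p = 2.29e-08, and adjusted p = 0.514 with an estimated correlation). DNA replication (7 of 24 lower, 14 adjusted over the list alone, median -0.56) and ribosome biogenesis genes (8 of 24, 13 adjusted over the list alone, median -0.34) moved the same way, each with a camera adjusted p = 7.77e-05 and an adjusted p = 0.670 and 0.514 with an estimated correlation. With epithelial scaling these medians were -0.31 and -0.095. Interferon genes (15 of 24 lower, 17 adjusted over the list alone, median -1.25) and tuft cell genes (11 of 17 lower, with 11 lower and 1 higher adjusted over the list alone, median -1.75) also had the lower sort effect in AKVPSL, with camera adjusted p = 3.21e-08 and 8.32e-05, and an adjusted p = 0.514 with an estimated correlation for both. The fetal and regenerative list differed in 6 of 16 genes (6 adjusted over the list alone, median -0.55, camera adjusted p = 0.00819, and adjusted p = 0.514 with an estimated correlation), including Ly6a, which went from 222.2 to 311.1 CPM from GFP- to GFP+ in AKVPL and from 1058 to 434.7 CPM in AKVPSL. The fetal and regenerative median was -0.30 with epithelial scaling, -0.30 without AKVPL GFP+ replicate 3 and -0.35 without AKVPSL GFP- replicate 3. Epithelial identity genes differed in 9 of 18, all more negative in AKVPSL (10 adjusted over the list alone, median -0.43, or -0.17 with epithelial scaling, camera adjusted p = 0.00365, and adjusted p = 0.514 with an estimated correlation). Antigen presentation genes differed in 6 with a more negative and 1 with a more positive effect of 16 (8 and 1 adjusted over the list alone, median -0.76), and Paneth cell genes in 3 with a more positive and 1 with a more negative effect of 6 (4 and 1 adjusted over the list alone, median 1.25). Camera gave an adjusted p = 0.0146 and 0.00642, and an adjusted p = 0.670 and 0.514 with an estimated correlation. The antigen presentation call ended on the deposited RPKM values (-0.32 on that scale).

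Among single genes with the smallest adjusted p, the sort effect was more positive in AKVPSL for the potassium channel Kcnh2 (2.53 ± 0.20), for Pcdhgc3, Pcdhgc5 and Pcdhga1 (1.89 ± 0.16, 1.76 ± 0.15 and 1.75 ± 0.15) and for Car8. The protocadherin genes share exons, so their counts may hold the same reads and they stand here for 1 locus. Car8 had 2 counts over AKVPL GFP+ against 128 in AKVPL GFP-, 84.9-fold lower with a 95% counting interval of 23.0 to 708.6, while in AKVPSL the group means were 4.08 ± 1.37 CPM in GFP+ and 0.82 ± 0.35 CPM in GFP- cells (SD, n = 4). The sort effect was more negative in AKVPSL for Myl9 (-2.65 ± 0.24), Ly6a (-1.77 ± 0.17), AA986860 (-1.63 ± 0.16), the cell cycle inhibitor Cdkn2a (-1.66 ± 0.17) and Fndc5, which had 0 counts over AKVPSL GFP+ against 56 in AKVPSL GFP-, at least 23.8-fold lower when 3 counts over the group are taken as the floor. In all 3743 of 18072 genes differed in their sort effect by edgeR's test, 1267 with a more positive and 2476 with a more negative effect in AKVPSL. The share of more positive effects was 33.85% with TMM, 49.21% with DESeq2 size factors, 44.25% with library totals and 75.31% with epithelial size factors, which moved the median of all genes by 0.26. Lgr5 itself did not differ past the threshold (-0.18 ± 0.21).

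**Figure D3:**
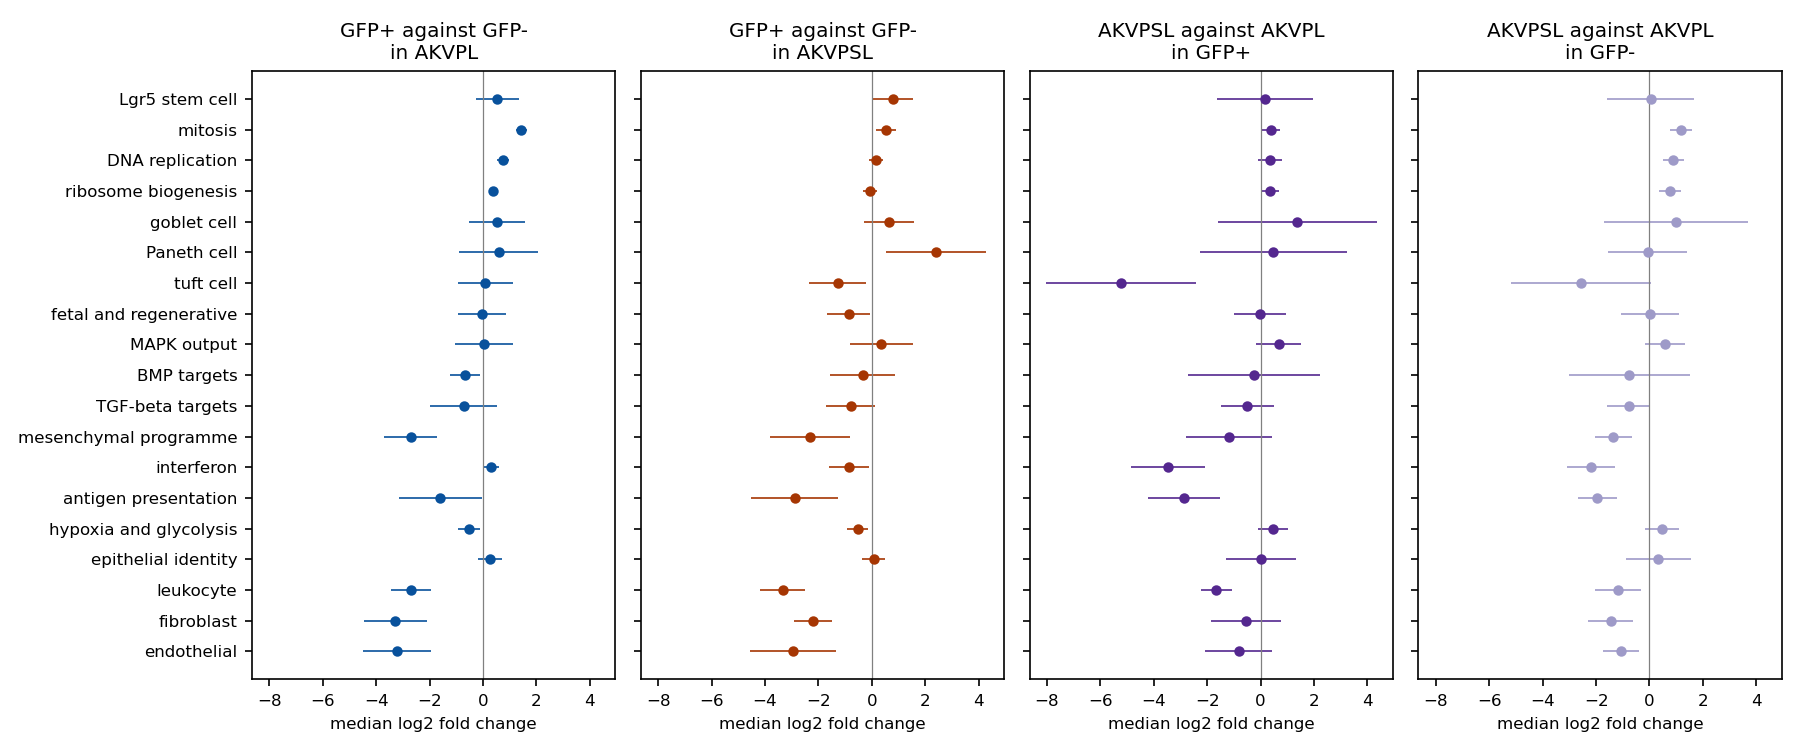
Median log2 fold change (x axis, one range for all panels) of 19 gene lists (y axis) in the 4 comparisons between groups; points are medians over the genes of a list and bars are the SD over those genes. The tuft cell list has a median of -5.22 and the interferon list of -3.46 between genotypes in GFP+ cells, and the leukocyte, fibroblast and endothelial lists lie below 0 in both sort comparisons.

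The third comparison set AKVPSL against AKVPL in GFP+ cells, a contrast of the 2 genotypes within the Lgr5 sort. Genes of tuft cells, the interferon response and antigen presentation were lower in the libraries labelled AKVPSL, and genes downstream of MAPK signalling were higher. All 17 tuft cell genes fell (17 adjusted over the list alone; median -5.22, SD 2.81): Dclk1 stood at 255 ± 38.6 CPM (SD, n = 4) in AKVPL and 0.49 ± 0.30 CPM in AKVPSL (-9.11 ± 0.25, SE). The ion channel Trpm5 fell by -7.86 ± 0.25 and Sh2d6 by -8.87 ± 0.29. Chat, the enzyme of acetylcholine synthesis, had 667 counts over the AKVPL group and 0 over AKVPSL, at least 258-fold lower. The median was -5.22 as well with such genes at their bound. The list's camera adjusted p was 2.85e-12, and its adjusted p = 0.248 with an estimated correlation. Of 24 interferon response genes 23 fell (23 adjusted over the list alone; median -3.46, SD 1.40, camera adjusted p = 1.61e-16, and adjusted p = 0.248 with an estimated correlation), with Cxcl10 at -0.01 as the member that did not pass. Oas2 fell by -6.52 ± 0.25 and Usp18 by -3.45 ± 0.16. Of 16 antigen presentation genes 15 fell (15 adjusted over the list alone; median -2.88, camera adjusted p = 9.87e-07, and adjusted p = 0.700 with an estimated correlation), with Nlrc5 at -5.44 ± 0.25, the peptide transporter Tap1 at -4.20 ± 0.26 and B2m, the light chain of class I molecules, at -1.65 ± 0.16. Leukocyte genes were also lower, 14 of 22 (14 adjusted over the list alone; median -1.66, SD 0.58, camera adjusted p = 0.00368, and adjusted p = 0.700 with an estimated correlation), a call that ended with the DESeq2 Wald test. The antigen presentation list also holds class II genes of antigen-presenting cells, such as Cd74 and H2-Ab1. Between the sorts it fell in GFP+ with the leukocyte list, with medians of -1.59 and -2.70 in AKVPL and -2.89 and -3.34 in AKVPSL. Leukocyte content as a source of its genotype difference was not tested. Xist was lower by -1.22 ± 0.38 on the log2 scale (edgeR adjusted p = 0.0154).

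Of 19 genes of MAPK output 12 rose and 1 fell (12 and 1 adjusted over the list alone; median 0.68, SD 0.85, camera adjusted p = 0.000186, and adjusted p = 0.472 with an estimated correlation), the feedback inhibitors Spry1, Spry4 and Spred1 by 1.42 ± 0.07, 2.10 ± 0.18 and 1.22 ± 0.09 and the transcription factor Etv5 by 1.70 ± 0.13. Ribosome biogenesis genes rose in 14 of 24 (15 adjusted over the list alone; median 0.36) and hypoxia and glycolysis genes in 13 of 24 with 1 that fell (13 and 1 adjusted over the list alone; median 0.46), with camera adjusted p = 0.00204 and 0.0042, and an adjusted p = 0.700 with an estimated correlation for both. Mitosis genes rose in 11 of 24 with 1 that fell (11 and 1 adjusted over the list alone; median 0.40, camera adjusted p = 0.0195, and adjusted p = 0.700 with an estimated correlation), a call that ended without AKVPL GFP+ replicate 3 (median 0.32), AKVPSL GFP+ replicate 1 (0.37) or AKVPSL GFP+ replicate 2 (0.34), with the stricter low-count filter and with the DESeq2 Wald test. The BMP and TGF-beta target lists did not pass camera's test. The goblet cell list passed only with no low-count filter (median 1.40) and the WNT target list only with no filter (0.38) and without AKVPL GFP+ replicate 4 (0.37). Members of these 4 lists moved both ways. Id1 and Id3 fell by -4.14 ± 0.19 and -3.04 ± 0.13 and Pmepa1, a TGF-beta target, by -1.85 ± 0.12, while Id4 rose by 3.52 ± 0.22 and Bmp4 by 1.81 ± 0.14. Tff3 and Spink4 rose by 4.69 ± 0.30 and 3.85 ± 0.27, while Galnt12, a mucin glycosyltransferase, fell by -4.54 ± 0.23. Of the WNT feedback genes Nkd1 rose by 2.01 ± 0.12 and Notum by 1.06 ± 0.12, while Sp5 fell by -2.29 ± 0.26.

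Among the genes with the largest fall between genotypes in GFP+ cells, Zp2 and Hmx3 had 833 and 777 counts over the AKVPL group and 0 over AKVPSL, at least 322- and 301-fold lower. Lipf, a gastric lipase, had 2607 against 1, 3028-fold lower with a 95% counting interval of 543 to 119700. In the other direction Cldn6, a claudin, rose by 6.72 ± 0.17, Wfdc2 by 6.80 ± 0.57, Cxcl15 by 7.44 ± 0.37, Ank2 by 6.85 ± 0.39 and Rhox5, a homeobox gene of the X chromosome, by 7.88 ± 0.79. Cdx2, a homeobox factor of intestinal identity, stood at 40.2 ± 6.34 CPM in AKVPSL and 1.48 ± 0.27 CPM in AKVPL (4.75 ± 0.28). Krt14, a keratin of squamous epithelium, fell by -7.19 ± 0.29, and Hoxa10, a gene of posterior gut, by -3.00 ± 0.37. In total 9584 of 18072 genes changed by edgeR's test, 4502 higher and 5082 lower in AKVPSL, of which 1376 and 2942 by 2-fold or more. The 8 libraries separated by genotype for 51.28% of genes, where chance gives 2.857%.

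The fourth comparison set AKVPSL against AKVPL in GFP- cells. The tuft cell, interferon and antigen presentation genes were lower in AKVPSL here as well, and genes of cell division and ribosome biogenesis were higher. Leukocyte content was not tested as a source of the antigen presentation difference here either. Of 17 tuft cell genes 16 fell (16 adjusted over the list alone; median -2.56, SD 2.64), of 24 interferon genes 23 (23 adjusted over the list alone; median -2.19, SD 0.90) and of 16 antigen presentation genes 16 (16 adjusted over the list alone; median -1.96, SD 0.73). The 3 lists had a camera adjusted p = 4.65e-09, 1.10e-11 and 1.33e-06, and each had an adjusted p = 0.570 with an estimated correlation. Dclk1 fell by -6.51 ± 0.21, Trpm5 by -7.55 ± 0.24, Irf9 by -2.06 ± 0.11, Nlrc5 by -2.50 ± 0.20 and Tap1 by -1.98 ± 0.23. Mitosis genes rose in 24 of 24 (24 adjusted over the list alone; median 1.18, SD 0.41), DNA replication genes in 21 of 24 (22 adjusted over the list alone; median 0.90) and ribosome biogenesis genes in 21 of 24 (21 adjusted over the list alone; median 0.75). For these the camera adjusted p was 1.37e-07, 6.39e-06 and 2.76e-07, and for each the adjusted p = 0.570 with an estimated correlation. With epithelial scaling the medians of DNA replication and ribosome biogenesis genes were 0.575 and 0.435. Cenpa, the histone of centromeres, rose by 2.11 ± 0.15, Mcm7, a replication helicase subunit, by 1.32 ± 0.11 and nucleolin (Ncl) by 1.08 ± 0.09.

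Leukocyte and fibroblast marker lists differed between the genotypes in GFP- cells too. Of 20 fibroblast genes 17 fell and 1 rose (19 and 1 adjusted over the list alone; median -1.46, SD 0.84) and of 22 leukocyte genes 10 fell (6 adjusted over the list alone; median -1.17, SD 0.87), with a camera adjusted p = 0.000401 and 0.00279. They had an adjusted p = 0.599 and 0.678 with an estimated correlation. Neither list passed with the DESeq2 Wald test. Pdgfra stood at 6.16 ± 3.00 CPM in AKVPSL and 33.8 ± 6.63 CPM in AKVPL GFP- cells (SD, n = 4). In GFP+ cells it stood at 3.01 ± 1.42 CPM in AKVPSL and 29.15 ± 5.94 CPM in AKVPL. Its genotype difference was thus not particular to the GFP- sort. The endothelial list (5 of 14 fell and 2 rose, median -1.07) did not pass in the fit of all libraries, and passed with no low-count filter and without AKVPL GFP- replicate 2 (-1.19) or 4 (-1.17) or AKVPSL GFP- replicate 1 (-1.31) or 2 (-1.49). Beside them, mesenchymal programme genes fell in 9 of 11 (9 adjusted over the list alone; median -1.35) and TGF-beta targets in 14 of 21 with 2 that rose (14 and 3 adjusted over the list alone; median -0.78), with camera adjusted p = 0.00498 and 0.00438 and an adjusted p = 0.570 with an estimated correlation for both. Fibronectin (Fn1) fell from 7779 ± 654 to 1948 ± 481 CPM (SD, n = 4), and in GFP+ cells from 6965 ± 940 to 3078 ± 884 CPM. MAPK output genes rose in 11 of 19 with 1 that fell (11 and 1 adjusted over the list alone; median 0.57, camera adjusted p = 0.0256, and adjusted p = 0.570 with an estimated correlation), with Spry1 at 1.07 ± 0.07; that call ended with the stricter low-count filter, and the median was 0.25 with epithelial scaling. Epithelial identity genes rose in 10 of 18 and fell in 2 (10 and 2 adjusted over the list alone, median 0.34, camera adjusted p = 0.0256, and adjusted p = 0.570 with an estimated correlation). The epithelial call ended with the stricter filter, in the fit of these 8 libraries alone and, by construction, with epithelial scaling. Cholesterol biosynthesis genes rose in 12 of 23 with 1 that fell (12 and 1 adjusted over the list alone; median 0.33, camera adjusted p = 0.0181, and adjusted p = 0.678 with an estimated correlation), with Cyp51 at 1.16 ± 0.13. That call ended without AKVPSL GFP- replicate 1 (median 0.26), with the stricter low-count filter and with the DESeq2 Wald test, and the median was -0.004 with epithelial scaling. The fetal and regenerative genes Ly6a and Anxa3 rose by 2.25 ± 0.12 and 1.97 ± 0.10, Myc by 1.42 ± 0.14 and Sox9 by 1.22 ± 0.11, while the lists that hold them did not pass camera's test. Cdx2 rose by 3.90 ± 0.28 and Gpx2 by 2.67 ± 0.15.

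At the extremes, Wfdc2 rose by 7.53 ± 0.59 and Cldn6 by 7.43 ± 0.18, while Lipf, Nsg2, Zp2 and Dmbt1 had 1158, 628, 654 and 683 counts over AKVPL GFP- and 0 over AKVPSL GFP-, at least 467-, 253-, 264- and 276-fold lower. Reg3b, an antimicrobial lectin, fell by -9.95 ± 0.76 and Gnb3 by -9.88 ± 0.34. In GFP- cells 11328 of 18072 genes changed by edgeR's test, 5786 higher and 5542 lower in AKVPSL, of which 1973 and 3318 by 2-fold or more. The libraries separated by genotype for 53.19% of genes, where chance gives 2.857%. Higher genes made up 51.08% of the calls with TMM and 29.71% with epithelial size factors, which moved the median of all genes by -0.32. Library totals moved it by -0.11. Calls in both sorts shared 3410 genes higher and 3708 lower in AKVPSL, where independent lists would share 1441.4 and 1558.5, and 211 genes were called in opposite directions.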

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

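The tests on dilution, host cells, a mesenchymal programme, leukocyte content and differences between tumour lines were chosen after the results were seen; the counts of other splits of the libraries were planned.

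The first pattern is the higher level of mitosis genes in GFP+ cells. RNA from other cells in the GFP- libraries could dilute tumour transcripts there and raise every tumour gene in GFP+. With libraries scaled on the epithelial list, the mitosis median was 1.12 in AKVPL, where the SD over the epithelial genes was 0.46, and 0.46 in AKVPSL, where it was 0.43. Both lists kept camera's call with the preset correlation, which ended with an estimated correlation in the fit with TMM (adjusted p = 0.162 and 0.433). Dilution as the whole cause needs the epithelial genes to rise as much as the mitosis genes, whose medians were 1.44 and 0.53 with TMM, but those of the epithelial genes were 0.27 and 0.07. That argues against it as the whole cause, by a narrow margin in AKVPSL. A difference in proliferation between the sorts remains open as a hypothesis, since dividing cells may also differ in GFP signal and no measure of cell cycle other than RNA was used here.

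The second pattern is the higher level of stromal and leukocyte genes in GFP- cells. Host cells among the sorted GFP- cells are a candidate source that the values leave open. In AKVPL GFP- cells Col1a1 stood at 2413 CPM and Cd74 at 2428 CPM. Xist fell with these genes, by -2.97 in AKVPL and -2.83 in AKVPSL on the log2 scale, but this decides nothing: the 4 Y-linked genes read held 1 count over 16 libraries, so no difference in sex marks Xist as a transcript of host cells. A mesenchymal programme in the tumour cells does not account for leukocyte genes, whose medians were -2.70 (SD over genes 0.76) and -3.34 (SD 0.84). It is argued against as the whole cause only because the pattern was drawn to include these genes. Their medians are no separate test and say nothing about the stromal genes. The programme remains open for the mesenchymal and TGF-beta genes. Of the 22 leukocyte genes 1 (Cd74) is also on the antigen presentation list.

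The third pattern is the lower level of interferon genes in the libraries labelled AKVPSL. Fewer host leukocytes there could lower such genes, but within AKVPL the interferon median was 0.29 (SD 0.31) where the leukocyte median was -2.70 (SD 0.76), so there interferon RNA did not follow leukocyte RNA. Within AKVPSL it fell with leukocyte RNA, with medians of -0.86 (SD 0.76) and -3.34 (SD 0.84). The level to be explained is the higher one of AKVPL, so fewer leukocytes are argued against as the whole cause, and a part of the difference in GFP- cells stays open. A difference between the tumour lines other than the S allele cannot be told apart from the genotype, since the labels give no number of lines. Genes above 10 CPM in all 8 libraries of one genotype and under 1 CPM in all 8 of the other numbered 15; with the lower limit at 0.1 CPM, tried first, there were 0, and the limit of 1 CPM was set after that count was seen. An effect of the genotype itself remains open and untested.

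Other splits of the same libraries were tested for each count of changed genes, 35 in each case, and only the real split gave as many genes, 1 of 35 each time. The real counts and the highest of the other splits were 7070 and 37 for the sort in AKVPL, 8494 and 1657 for the sort in AKVPSL, 9584 and 0 between genotypes in GFP+, 11328 and 14 between genotypes in GFP-, and 3743 and 0 for the difference of sort effects. Chance in the grouping of these libraries can be excluded at that level for the 2 counts between genotypes. For the 2 sort counts that holds only with the libraries taken as unpaired. Since separate animals or tumours are not stated, chance between tumours is not covered. For the difference of sort effects the splits decide nothing. Every other assignment there put libraries of both genotypes into 1 group, and the genotype difference then raised the spread. The AKVPSL split with 1657 genes exchanged GFP+ replicate 2 with GFP- replicate 4, and the split of replicates 1 and 2 from replicates 3 and 4 called 187, which points to a structure among those libraries. With the replicate numbers taken as pairs, 8 splits part all pairs, too few for a share under 0.05; the highest count among them other than the real one was 0 in both genotypes.

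In 9 of 132 groups of 4 libraries, 1 library lay far from the others, where chance gives about 1 in 20 groups. The measures were chosen after the data were seen, and Muc2, Isx, Krt36 and Ly6g because 1 library stood out in them. Lyz2 stood at 473.8 CPM in AKVPL GFP+ replicate 3 against 178.4 to 218.2 CPM in the others. Epcam stood at 1998 CPM in AKVPL GFP+ replicate 1 (others 1879 to 1895) and at 1795 CPM in AKVPSL GFP- replicate 4 (others 1964 to 1990). Cdx2 stood at 1.89 CPM in AKVPL GFP+ replicate 2 (others 1.29 to 1.39) and Anxa3 at 1067 CPM in AKVPSL GFP- replicate 3 (others 863.6 to 897.3). In AKVPL GFP- replicate 2, Muc2 stood at 17.6 CPM (others 0.35 to 0.51), Isx at 4.08 CPM (others 0.035 to 0.24), Krt36 at 6.18 CPM (others 0.097 to 0.42) and Ly6g at 6.66 CPM (others 0.18 to 0.51).

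Over all 18072 genes, the sort effect differed between the genotypes for 20.71%. The share among named genes cannot be set against that, since most were picked for their changes in these data. The 5 genes each way with the smallest adjusted p of this difference pass by selection. Of 81 named genes reported here, 42 had a sort effect that differed between the genotypes past the threshold of edgeR's test, given here as log2 differences, AKVPSL minus AKVPL. Among secretory and absorptive genes they were Ang4 5.68, Reg4 2.78, Clca3b 2.65, Tff3 1.45, Spink4 1.13, Mmp7 0.86, Muc4 -0.78, Bglap3 -4.96, S100g -3.47, Tspan8 -1.46, Cdh17 -0.90 and Krt19 -1.11. Chgb, a granule protein of endocrine cells, differed by 4.96. Among stem cell, signalling and fetal genes they were Smoc2 0.49, Etv5 0.62, Id1 -1.45, Id3 -0.59, Krt7 -0.97, Anxa3 -1.13, Ly6a -1.77 and Ly6d -1.14. Mitosis genes gave Nusap1 -0.71, Ube2c -1.12 and Cenpe -0.81. Tuft, interferon and antigen presentation genes gave Dclk1 -2.59, Hpgds -1.80, Ifit3 -2.61, Irf7 -1.95 and Nlrc5 -2.94. The others were Stac 1.80, Sema4g 1.70, Twist1 3.62, Kcnh2 2.53, Pcdhgc3 1.89, Pcdhgc5 1.76, Pcdhga1 1.75, Myl9 -2.65, AA986860 -1.63 and Cdkn2a -1.66. The fitted values of Car8 (8.32), Fndc5 (-8.50) and Tph1 (-4.01) rest on a group with 3 or fewer counts and depend on the prior count of the fit. Low counts limit others too, among them Bglap3 (24 and 7 counts over AKVPSL GFP- and GFP+) and S100g (22 and 12 there). Ang4 had 37 and 9 counts over AKVPL GFP- and GFP+, and Chgb had 12 over AKVPL GFP+.

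For 15 lists the sort effect differed between genotypes by camera's test with the preset correlation, and for 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05 and fry gave 15. The medians were 0.19 for stem cell, -0.55 for fetal, 1.25 for Paneth, -1.75 for tuft, -0.92 for mitosis, -0.56 for DNA replication, -0.34 for ribosome biogenesis, 0.29 for MAPK output, -1.25 for interferon, -0.76 for antigen presentation, 0.13 for ER stress, 0.28 for dissociation stress, -0.43 for epithelial, 1.01 for fibroblast and 0.29 for endothelial genes. Without AKVPL GFP- replicate 4 or AKVPSL GFP+ replicate 3 the stem cell median was 0.11 and 0.086. The MAPK call ended without AKVPL GFP+ replicate 4 (0.24), and its median was 0.15 to 0.18 without AKVPL GFP- replicate 3, AKVPSL GFP+ replicate 2 or 4, or AKVPSL GFP- replicate 3. That of ER stress ended without AKVPSL GFP- replicate 4 (0.085) and on RPKM (0.24), and its median was 0.044 to 0.23 without AKVPL GFP+ replicate 3 or 4, AKVPL GFP- replicate 3 or AKVPSL GFP+ replicate 1. Epithelial scaling raised the medians of the stem cell, MAPK, ER stress and dissociation stress lists to 0.46, 0.55, 0.40 and 0.54. The fibroblast call ended without AKVPL GFP+ replicate 1 (0.83), AKVPSL GFP+ replicate 4 (0.42) or AKVPSL GFP- replicate 2 (0.85). The endothelial call ended without AKVPL GFP+ replicate 2 (0.05), AKVPL GFP- replicate 1 (0.08), AKVPSL GFP+ replicate 2 (-0.05), AKVPSL GFP- replicate 3 (0.09) or AKVPSL GFP- replicate 4 (0.05), with the DESeq2 Wald test (0.38) and with epithelial scaling (0.55). Its median was 0.18 to 0.63 without AKVPL GFP+ replicate 3 or 4, AKVPSL GFP+ replicate 3 or AKVPSL GFP- replicate 1 or 2. The dissociation stress call ended in 8 of the fits with a library left out, with medians from 0.21 to 0.25, with the DESeq2 Wald test (0.37) and on RPKM (0.42).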

How the results depend on the processing

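Epithelial size factors and limma-trend on RPKM were chosen after the data were seen; the other alternatives were planned. All 5 counts of changed genes stayed within 1.5 times their main value under each alternative. Leaving out 1 library gave 5817 to 6961 genes for the sort in AKVPL, 7244 to 8709 for the sort in AKVPSL, 8684 to 9359 and 10652 to 11355 between genotypes in GFP+ and GFP-, and 2818 to 4646 for the difference of sort effects. Called lists then numbered 21 to 23, 19 to 21, 7 to 10, 13 to 15 and 13 to 18. With the replicate block, paired by number, the counts were 7902, 9266, 9938, 11647 and 4735. In the sort comparisons, taken as paired, the block made 2 lists of AKVPSL pass, erythroid genes (-2.11) and small intestine regional genes (0.58). In the difference of sort effects it made WNT target genes (0.23) and squamous genes (-0.75) pass, and it changed no other call in these 3 comparisons. Across genotypes, where numbers were not taken as pairs, Trp53 (-0.31) and the lists of DNA replication (0.34) and NF-kappa-B and inflammation genes (-0.50) passed in GFP+ with the block. With an estimated correlation 0 lists passed in each of the 5 comparisons, against 23, 20, 8, 13 and 15 with the preset value. Unadjusted p was under 0.05 for 7, 4, 3, 2 and 1 lists with the estimate, and for 27, 26, 26, 28 and 15 with fry. Without a low-count filter 13 lists passed between genotypes in GFP+ cells, against 8; the cause was not tested. The difference of Smad4 between the sort effects passed with the DESeq2 Wald test (0.42), without AKVPSL GFP- replicate 4 (0.41), with epithelial size factors (0.59) and on RPKM (0.40). Over all alternatives, the named genes reported here kept direction and side of the threshold in 3732 comparisons, lost the call in 14 and gained it in 11; lists kept theirs in 3045, lost in 146 and gained in 85. limma-voom gave no separate list value, the fit of the compared groups alone gave none for the difference of sort effects, and pseudocount alternatives planned for normalized values were not run because counts were used. Depth limits genes with 0 counts over a group, whose folds are bounds, and genes with 1 to 3, whose folds have wide counting intervals.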

Other observations

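The test of chromosome shifts was planned before its result was seen.

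Gene lists not described so far also differed between GFP+ and GFP- cells. NF-kappa-B and inflammation genes fell in GFP+ cells in 10 of 21 in AKVPL (10 adjusted over the list alone, median -0.76, camera adjusted p = 5.42e-05) and in 13 of 21 in AKVPSL (14 adjusted over the list alone, median -0.83, camera adjusted p = 0.000268). With an estimated correlation the adjusted p = 0.210 and 0.315. Targets of p53 fell in 8 of 18 and rose in 1 in AKVPL (8 and 1 adjusted over the list alone, median -0.35, camera adjusted p = 0.00844, and adjusted p = 0.162 with an estimated correlation). ER stress genes fell in 13 of 20 in AKVPL (13 adjusted over the list alone, median -0.37, camera adjusted p = 8.06e-05, and adjusted p = 0.162 with an estimated correlation). Squamous genes fell in 5 of 11 in AKVPSL (5 adjusted over the list alone, median -0.83, camera adjusted p = 0.018, and adjusted p = 0.274 with an estimated correlation), a call that ended without AKVPSL GFP+ replicate 1 (-0.79); without AKVPSL GFP+ replicate 2 the median was -1.49. With epithelial scaling the medians of p53 targets and ER stress genes in AKVPL were -0.68 and -0.70.

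In AKVPL, enteroendocrine genes fell in 5 of 9 and rose in 1 (5 and 1 adjusted over the list alone, median -1.51, camera adjusted p = 0.0141, and adjusted p = 0.162 with an estimated correlation), a call that ended with epithelial scaling and on the deposited RPKM values; without AKVPL GFP- replicate 1 the median was -0.67. Genes of muscle and fat fell in 7 of 11 in AKVPL (7 adjusted over the list alone, median -1.79) and in 6 of 11 in AKVPSL (6 adjusted over the list alone, median -1.62), with camera adjusted p = 0.000642 and 0.0323 and an adjusted p = 0.162 and 0.274 with an estimated correlation. The AKVPSL call ended without AKVPSL GFP+ replicate 1 (-1.65) or AKVPSL GFP- replicate 1 (-1.52) and on the RPKM values. Erythroid genes fell in 1 of 6 in AKVPL (1 adjusted over the list alone, median -1.12, camera adjusted p = 0.0358, and adjusted p = 0.423 with an estimated correlation). That call ended without AKVPL GFP+ replicate 1 (-0.90) or AKVPL GFP- replicate 4 (-0.85), with DESeq2 size factors, library totals or epithelial scaling, with the DESeq2 Wald test and on the RPKM values. Small intestine regional genes rose in 5 of 7 in AKVPL (6 adjusted over the list alone, median 0.81, or 0.45 with epithelial scaling, camera adjusted p = 0.0172, and adjusted p = 0.162 with an estimated correlation). Dissociation stress genes, a sign of handling, fell in 3 of 20 in AKVPL (2 adjusted over the list alone, median -0.12, camera adjusted p = 0.0491, and adjusted p = 0.592 with an estimated correlation). That call ended without AKVPL GFP+ replicate 1 (-0.05) or 4 (-0.02) or AKVPL GFP- replicate 2 (-0.08) or 3 (-0.06), with the DESeq2 Wald test and on the RPKM values. Its median was -0.19 to -0.245 without AKVPL GFP+ replicate 2 or 3 or AKVPL GFP- replicate 1, and -0.45 with epithelial scaling. Cholesterol biosynthesis genes fell in 10 of 23 and rose in 1 in AKVPSL (10 and 1 adjusted over the list alone, median -0.23, camera adjusted p = 0.0434, and adjusted p = 0.627 with an estimated correlation). That call ended without AKVPSL GFP+ replicate 3 (-0.14) or 4 (-0.14) or AKVPSL GFP- replicate 1 (-0.11), with the DESeq2 Wald test and in the fit of these 8 libraries alone. Its median was -0.39 without AKVPSL GFP+ replicate 1 and -0.35 without AKVPSL GFP- replicate 4.

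In AKVPSL GFP-, the mean log2 CPM of the endothelial list was 5.08, 5.25, 3.50 and 3.54 and that of the leukocyte list 4.33, 4.49, 6.01 and 5.30 in replicates 1, 2, 3 and 4. Over 16 libraries the 4 Y-linked genes read held 1 count in all.

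A hypothesis of copy number differences between the tumours behind the genotypes was tested on chromosome medians. On 4 chromosomes the median log2 difference between genotypes lay more than 0.3 from that of all genes in both sorts: chromosome 5 (0.53 in GFP+ and 0.50 in GFP-), 12 (0.34 and 0.34), 15 (0.39 and 0.34) and 18 (0.52 and 0.49). Between sorts the chromosome medians ran from -0.04 to 0.05 in AKVPL and from -0.06 to 0.15 in AKVPSL. Smad4 and Apc lie on chromosome 18 and Cdx2 on chromosome 5, so part of their difference between genotypes may follow the dosage of the chromosome. RNA alone does not measure copy number, and DNA was not analysed here.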
